A study of Mus musculus with 6 samples.

How the data were processed

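Small RNA libraries were made from skin tissue of C57 mice with a normal or a diabetic ulcer, labelled day 14. Per the labels' protocols, small RNA was extracted with a mirVana kit, and libraries were made for an Illumina platform. GRCm38 and mm10, 2 names of 1 mouse genome build, are named per the submitters' processing notes; the aligner, the counting tool and the miRNA annotation release are not given in the sources used here. Each sample was assigned to its group by its title, and each table column to a sample by the code in the title. All numeric columns were mapped, and 0 were left over.

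The deposited count table holds whole-number read counts per mature miRNA, with no normalization, for 649 entries, some of which merge miRNAs of identical sequence. The authors' TPM values divide the count by 1 constant per column in 4 of 6 columns, so they hold no length term. The listed miRNAs make up 42.0%, 63.8%, 44.1% and 48.1% of the total that the TPM values refer to in normal ulcer 1 and 2 and diabetic ulcer 1 and 2. The deposited comparison table gives a fold change, its log2 value, a p-value and a q-value, made with DESeq2 without pairing per the file headers. The base means and miRNA lengths in the deposited tables were read as other values, per the file headers. The count table and the comparison table each hold 2 entries that the other lacks.

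Columns were examined for dependence by robust least squares of each column on each pair of others, over miRNAs with at least 200 counts in any of the 3 columns (60 fits). A value was counted as met within 1% or 1 read. The authors' group means were fitted by nonnegative least squares on the 4 columns whose TPM is a fixed multiple of the count. This led to 4 libraries being treated as independent, and the fits over these 4 were added after seeing the data.

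The main test, fixed before the data were examined, was edgeR's quasi-likelihood F test (edgeR 4.0.16, glmQLFit and glmQLFTest, R 4.3.3) on the deposited counts of all 6 columns, with TMM scaling, filterByExpr at its defaults and group as the only term. Calls needed a Benjamini-Hochberg adjusted p under 0.05. TMM factors were 1.477, 0.628 and 0.968 for normal ulcer 1 to 3 and 1.239, 1.028 and 0.875 for diabetic ulcer 1 to 3. Standard errors of log2 differences were the difference over the square root of its F value. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between members and again with an estimated one, and with fry, over lists with at least 3 tested members. With an estimated correlation camera takes p from the residual degrees of freedom, which follow from the number of samples and were few here. Lists could hardly pass in that setting, so failure there does not weigh against a call. Group means and SDs are over libraries 1 and 2 of each group.

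The named miRNAs were fixed by rule before the data were examined. They are up to 10 called miRNAs with the smallest adjusted p in each direction (or, where fewer than 5 passed, the 5 with the smallest p, said not to pass), the 5 most abundant by mean CPM, and up to 4 tested members of each fixed list, called ones first and then the most abundant. The 21 lists cover epithelial, hair follicle, leukocyte, inflammatory, muscle, erythroid, vascular, stromal, miR-29, hypoxia, let-7, growth, senescence, imprinted, fat, pigment, neural, liver and gut, and wound miRNAs. The text names part of these list members.

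A share of counts has a 95% Wilson interval. A count of 0 allows up to 3 counts, which is 0.335, 0.224, 0.322 and 0.279 CPM in normal ulcer 1 and 2 and diabetic ulcer 1 and 2. These values are over the library totals, without TMM scaling. Sequences were matched exactly to the miRNA transcripts of GENCODE release M21 on GRCm38, with 86 of 87 named entries matched and 71 of them at 1 place. Coordinates count from 1.

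The code was tested on simulated data with 100 miRNAs changed 2-fold and 100 changed 4-fold, drawn from the real means and spread. For 3 against 3 libraries (438 miRNAs) it called 47.4% of 2-fold and 94.9% of 4-fold changes, and 2.8% of its calls were unchanged miRNAs. For 2 against 2 (443 miRNAs) these shares were 18.9%, 87.2% and 2.0%. The 3 against 3 shares are for 3 separate libraries per group, whereas the real columns numbered 3 follow from others. Over the 4 independent libraries, edgeR gave 4 real miRNAs an unadjusted p under 0.05, where 22.2 would be expected with no effect. The shares of changes called are therefore not shown to carry over to the real libraries. Camera called a list in 3 of 50 simulated tables with no effect and independent members. The column fit recovered simulated weights of 0.3 and 0.8, and put 2.8% of 400 miRNAs within 1% for an independent library.

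Alternatives were DESeq2 1.42.0, limma-voom, RLE, upper quartile and total-count scaling, no filter, a mean CPM of at least 10, removal of the 5 most abundant miRNAs or of the muscle and erythroid lists, the replicate number as a block, each sample left out, limma-trend on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 10), a 2-fold threshold and an estimated correlation. Those on the 4 libraries, including DESeq2 and the block, camera on the deposited TPM, and the estimated correlation in each setting of the lists other than the reported one were chosen after seeing the data. Column fits used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.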

Results

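Small RNA was sequenced from skin tissue of C57 mice, an inbred laboratory strain, with either a normal ulcer or a diabetic ulcer. All samples were labelled day 14, and 3 samples were deposited per group. MicroRNAs (miRNAs) are short RNAs that repress messenger RNAs, and the count table listed 649 mature miRNA entries. Total miRNA counts were 8949104, 13421603 and 11262554 for normal ulcer samples 1, 2 and 3. They were 9309055, 10762761 and 13150911 for diabetic ulcer samples 1, 2 and 3. Between 609 and 638 entries had at least 1 count in a given sample.

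The values of the sample numbered 3 in each group followed from those of the other samples of its group, so 4 libraries carried independent measurements. The count of normal ulcer 3 lay within 1 read of 0.5 times normal ulcer 1 plus 0.506 times normal ulcer 2 for 629 of the 638 miRNAs counted in it (98.6%). Around this sum, its variance was 0.0008 of the Poisson variance, whereas the lowest of 2000 simulated Poisson libraries gave 0.757. The TPM of diabetic ulcer 3 lay within 0.1% of 2.12 times diabetic ulcer 2 minus 1.00 times diabetic ulcer 1 plus 6.11 for 189 of 222 miRNAs (85.1%) with at least 200 counts in diabetic ulcer 2. Where diabetic ulcer 1 and 2 both had counts under 60 and differed, diabetic ulcer 3 equalled either of them for 286 of 307 miRNAs (93.2%). As a reference, diabetic ulcer 1 equalled normal ulcer 1 or 2 for 55 of 303 such miRNAs (18.2%). Among all 60 choices of a column and 2 others, the 54 that mixed the groups placed at most 10.7% of miRNAs within 1% of a linear formula. TPM was the count over 1 constant for 99.5% or more of the miRNAs in the libraries numbered 1 and 2, against 18.7% in normal ulcer 3 and 0.2% in diabetic ulcer 3. Group means below are therefore given over libraries 1 and 2 of each group (n = 2), and counts of calls and list results are given over all 6 columns and over the 4 independent libraries. Where library 1 or 2 of a group was left out of the 6 columns, the column numbered 3 of that group stayed in. Such a fit therefore does not fully remove the library. For miRNAs on the linear formula, diabetic ulcer 1, when left out, stayed in with a negative weight through diabetic ulcer 3. For the 21 miRNAs whose TPM in diabetic ulcer 3 equalled the mean of diabetic ulcer 1 and 2, its weight was positive. At low counts diabetic ulcer 3 mostly repeated either library. Nothing in the labels says that the samples came from separate animals, so p-values measure only the spread between these samples.

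**Figure D1:**
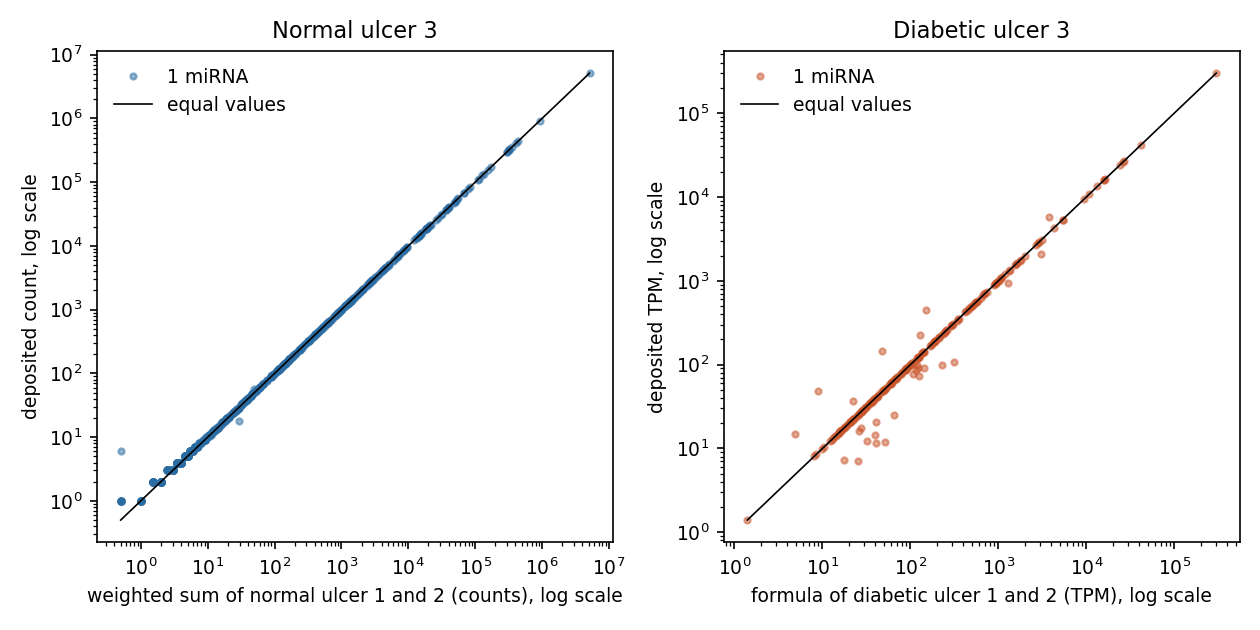
Deposited values of the samples numbered 3 against values computed from samples 1 and 2 of the same group, on log axes, with counts for normal ulcer 3 (left) and TPM for diabetic ulcer 3 (right). Each point is 1 miRNA and the line marks equal values; 98.6% of the counts lay within 1 read of the weighted sum, and 85.1% of the TPM values lay within 0.1% of the formula.

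The libraries were dominated by miR-1a-3p, a miRNA of skeletal and cardiac muscle. It took 16.42% of all counts in normal ulcer 1 (95% Wilson interval 16.40 to 16.45), 64.98% in normal ulcer 2 (64.95 to 65.01), 34.42% in diabetic ulcer 1 (34.39 to 34.45) and 44.40% in diabetic ulcer 2 (44.37 to 44.43). These intervals cover counting error only, since amplified reads are not independent molecules. Next in mean abundance were miR-26a-5p, miR-148a-3p, let-7i-5p and miR-27b-3p. miR-26a-5p had 85560 ± 2028 TMM-scaled CPM (counts-per-million values) in normal ulcer and 67500 ± 6000 in diabetic ulcer (SD, n = 2). For miR-148a-3p the means were 38800 ± 8715 and 47240 ± 16000 CPM, and for let-7i-5p they were 33360 ± 1389 and 36210 ± 5451 CPM (SD, n = 2). miR-27b-3p had 36980 ± 5554 CPM in normal ulcer and 33770 ± 6610 CPM in diabetic ulcer (SD, n = 2). The log2 difference of miR-1a-3p, diabetic minus normal, was -0.34 ± 0.76 (SE) over 6 columns, and it took a positive sign under limma-voom (0.11), library totals (0.02) and the deposited TPM (0.16), and without normal ulcer 2 (0.53).

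The libraries did not separate by group. Among the 4 independent libraries, the closest pair was normal ulcer 1 and diabetic ulcer 1, with a root mean square log2 difference of 0.49 across tested miRNAs. The next closest was normal ulcer 2 and diabetic ulcer 2 at 0.636. Within groups the distance was 0.865 between the normal ulcer libraries and 0.773 between the diabetic ulcer libraries.

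The comparison that the labels imply asks which miRNAs differed between diabetic and normal ulcer skin. Over the 6 columns, the smallest p-values toward diabetic ulcer belonged to miR-467c-5p, miR-7236-3p, miR-1a-1-5p, miR-130b-5p and miR-12191-3p. Toward normal ulcer they belonged to miR-3102-3p, miR-155-5p, miR-19b-3p, miR-29a-5p and miR-30e-5p. None of these 10 passed the test. For miR-467c-5p, miR-7236-3p, miR-130b-5p, miR-12191-3p and miR-29a-5p the column of diabetic ulcer 3 held the same count as diabetic ulcer 2. For miR-3102-3p it held the count of diabetic ulcer 1. The p-values that ranked these miRNAs therefore rest partly on a repeated count. miR-467c-5p, a member of a rodent miRNA cluster with near-identical copies, had 1.43 ± 0.00944 CPM in normal ulcer and 4.0 ± 1.12 CPM in diabetic ulcer (SD, n = 2). It rested on 19 and 12 counts in the normal libraries and 37 and 53 in the diabetic libraries, and reads may be split among its copies. Its log2 difference in edgeR was 1.53 ± 0.21 (SE) over 6 columns (adjusted p = 0.171) and 1.43 ± 0.42 over the 4 libraries (adjusted p = 0.999), and both diabetic libraries lay above both normal libraries. miR-1a-1-5p, the passenger strand of a miR-1 precursor, had 11.2 ± 2.79 CPM in normal ulcer and 19.8 ± 0.0419 CPM in diabetic ulcer (SD, n = 2). miR-155-5p, a miRNA of activated immune cells, had 138 ± 14.5 CPM in normal ulcer and 94.3 ± 3.11 CPM in diabetic ulcer (SD, n = 2). In edgeR its log2 difference was -0.61 ± 0.12 (SE) over 6 columns (adjusted p = 0.196) and -0.60 ± 0.24 over the 4 libraries (adjusted p = 0.999), and both diabetic libraries lay below both normal libraries. Such an order of the libraries is likely for miRNAs chosen by their smallest p and is no further support. miR-19b-3p, of the proliferation-associated miR-17-92 cluster, had 261 ± 52.0 CPM in normal ulcer and 153 ± 13.1 CPM in diabetic ulcer (SD, n = 2), a log2 difference of -0.82 ± 0.29 (SE) over the 4 libraries. miR-30e-5p had 299 ± 11.5 and 220 ± 4.28 CPM (SD, n = 2), in that order.

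The remaining 5 of these miRNAs were rare, at 0.502 to 4.26 CPM in the group means. miR-7236-3p had 0.502 ± 0.0388 CPM in normal ulcer and 1.29 ± 0.476 CPM in diabetic ulcer (SD, n = 2), on 4 to 18 counts per library. miR-130b-5p had 2.27 ± 0.530 and 4.26 ± 0.877 CPM, and miR-12191-3p had 1.28 ± 0.205 and 2.13 ± 0.313 CPM (SD, n = 2). miR-3102-3p had 2.37 ± 0.348 CPM in normal ulcer and 1.06 ± 0.219 CPM in diabetic ulcer, and miR-29a-5p had 3.55 ± 0.654 and 2.03 ± 0.316 CPM (SD, n = 2).

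With edgeR's quasi-likelihood test, 0 of 438 tested miRNAs passed an adjusted p of 0.05 over the 6 columns, and the smallest adjusted p was 0.171. At an unadjusted p under 0.05 there were 48 miRNAs, 25 higher and 23 lower in diabetic ulcer, where 21.9 would be expected with no effect. Over the 4 independent libraries, 0 of 443 passed, 4 had an unadjusted p under 0.05 (22.2 expected) and the smallest adjusted p was 0.999. On the 6 columns limma-voom called 0 (55 at an unadjusted p under 0.05) and DESeq2 called 6: miR-467c-5p, miR-1a-1-5p, miR-155-5p, miR-19b-3p, miR-30e-5p and the merged entry miR-669a-3p/miR-669o-3p, the last chosen after its values were seen. On the 4 libraries DESeq2 called 0, with 3 at an unadjusted p under 0.05. Without diabetic ulcer 1, edgeR called 5: miR-467c-5p, miR-7236-3p and, chosen after their values were seen, miR-129-2-3p, miR-3473h-5p and the merged entry miR-466a-3p/miR-466e-3p. There the diabetic group was diabetic ulcer 2 and the column numbered 3, with equal counts for miR-467c-5p (53 and 53) and miR-7236-3p (18 and 18). These 5 calls therefore rest on 1 independent diabetic library. A column that follows from others is no further measurement, so the tests over 6 columns count more samples than were measured independently.

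**Figure D2:**
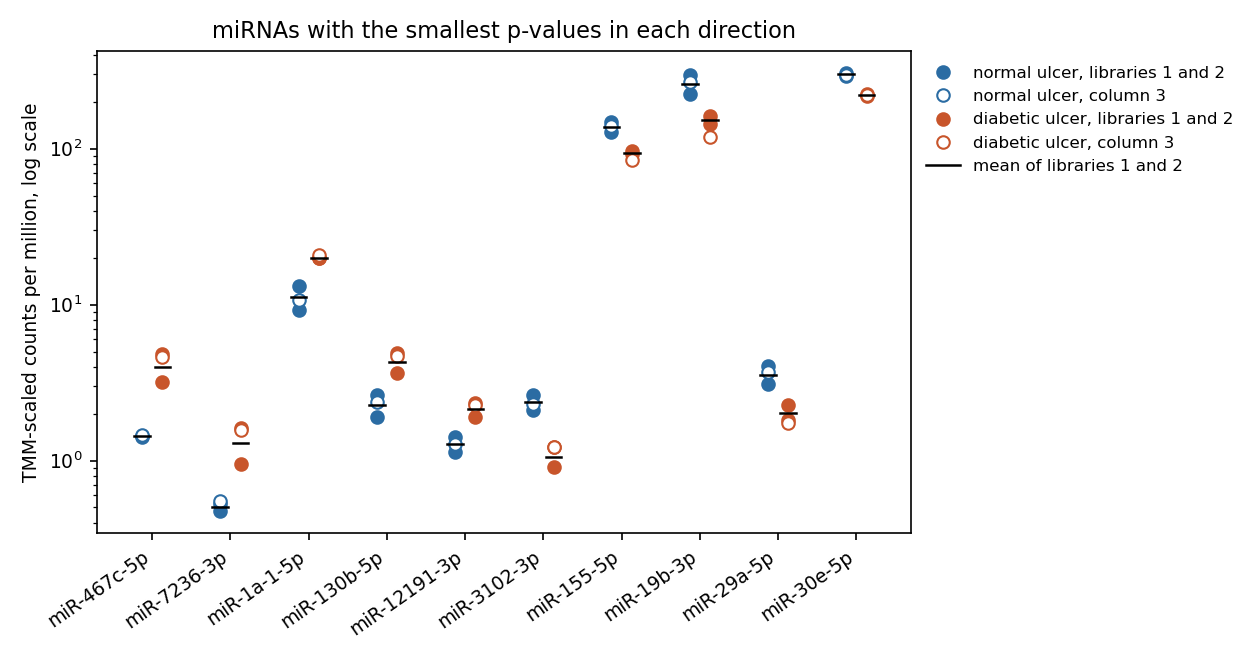
TMM-scaled CPM, on a log axis, of the 5 miRNAs with the smallest p-values in each direction. Filled points are libraries 1 and 2 of each group, open points are the columns numbered 3, and bars are means of libraries 1 and 2; for miR-467c-5p those means were 1.43 in normal ulcer and 4.0 in diabetic ulcer, and none of the 10 passed the test.

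Places are given on GRCm38 from an exact match of each mature sequence to annotated miRNA transcripts. miR-467c-5p (TAAGTGCGTGCATGTATATGTG) lies on chromosome 2 from 10473941 to 10473962, in an intron of Sfmbt2. miR-7236-3p (TTGGACCGCACAGATTTAGACC) lies on chromosome 11 from 121387145 to 121387166, in an intron of Rab40b. miR-1a-1-5p (ACATACTTCTTTATATGCCCATA) lies on chromosome 2 from 180389057 to 180389079, outside protein-coding and long non-coding genes. miR-130b-5p (ACTCTTTCCCTGTTGCACTACT) lies on chromosome 16 from 17124109 to 17124130, in an intron of 2610318N02Rik. miR-3102-3p (GAGCACCCCATTGGCTACCCACA) lies on chromosome 7 from 100882307 to 100882329 and overlaps an annotated exon of Arhgef17. miR-155-5p (TTAATGCTAATTGTGATAGGGGT) lies on chromosome 16 from 84714143 to 84714165, in an exon of the non-coding Mir155hg. miR-19b-3p (TGTGCAAATCCATGCAAAACTGA) has 2 places, on chromosome 14 from 115044358 to 115044380 in an exon of the non-coding Mir17hg and on chromosome X from 52741991 to 52742013, and its reads cannot be divided between them. miR-29a-5p (ACTGATTTCTTTTGGTGTTCAG) lies on chromosome 6 from 31062711 to 31062732, and miR-30e-5p (TGTAAACATCCTTGACTGGAAG) on chromosome 4 from 120772660 to 120772681 in an intron of Nfyc. miR-12191-3p had no exact match among the annotated miRNA transcripts. The abundant miR-1a-3p (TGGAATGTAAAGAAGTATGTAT) has 2 places, on chromosome 2 from 180389096 to 180389117 and on chromosome 18 from 10785485 to 10785506.

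miRNAs of the imprinted Dlk1-Dio3 cluster, a chromosome 12 region whose miRNAs are expressed from the maternal allele, had lower values in diabetic ulcer and were the list that camera called over 6 columns with its preset correlation. Of 42 tested members, 32 were lower and 10 higher in diabetic ulcer, with a median log2 difference of -0.27 and camera's adjusted p = 0.000118. Over the 4 libraries 35 of 42 were lower (median -0.22, adjusted p = 0.000437). On deposited TPM 25 were lower and 17 higher (median -0.09, where the median of all miRNAs was 0.14), or 24 and 18 with a pseudocount of 10 (median -0.03), with adjusted p = 0.0087 and 0.017. The call was lost in camera with an estimated correlation: adjusted p = 0.761 over 6 columns and adjusted p = 0.909 over the 4 libraries. Camera's unadjusted p for the cluster was 0.0434 and 0.0665 there, with estimated correlations of 0.064 and 0.023. That setting also raised camera's p for the miR-15-16 list over 6 columns, from 0.125 to 0.188, though its estimate of -0.082 lay below the preset 0.01. With an estimated correlation camera also uses fewer degrees of freedom, which raises p whatever the correlation. The loss is therefore not shown to come from correlation between members. fry, which tests whether members move on balance in 1 direction, gave adjusted p = 0.174 over 6 columns and adjusted p = 0.807 over the 4 libraries. Both diabetic libraries had a lower mean level of the cluster than both normal libraries (log2 level -0.05 and -0.14 against 0.02 and 0.17, relative to the mean of the 4 libraries). With 2 libraries per group, such an order can easily arise by chance. No member passed on its own with edgeR, and 8 had an unadjusted p under 0.05 over 6 columns and 0 over the 4 libraries. miR-127-3p, from 109592888 to 109592909 opposite an exon of Rtl1, had 2550 ± 114 CPM in normal ulcer and 2051 ± 86.3 CPM in diabetic ulcer (SD, n = 2). miR-381-3p had 394 ± 25.1 and 291 ± 30.7 CPM, and miR-541-5p had 395 ± 42.7 and 324 ± 28.0 CPM (SD, n = 2). miR-379-5p, another abundant member, had 1151 ± 171 and 1166 ± 78.7 CPM (SD, n = 2).

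Among 35 tested miRNAs of the wound repair and diabetic wound literature list, 23 were lower and 12 higher in diabetic ulcer over 6 columns (median log2 -0.25, camera's adjusted p = 0.0821). The list passed over the 4 libraries (25 lower, 10 higher, median -0.12, adjusted p = 0.044), and not there with its own correlation, where adjusted p = 0.909 with an estimated correlation. Leaving out single samples moved it from adjusted p = 0.0209 without normal ulcer 2 (there adjusted p = 0.716 with an estimated correlation) to adjusted p = 0.43 without normal ulcer 1, where 20 were lower and 15 higher (median -0.06). On deposited TPM with a pseudocount of 1 it was called (20 lower, 15 higher, median -0.07, adjusted p = 0.0259), and there adjusted p = 0.716 with an estimated correlation. It holds miR-21a-5p, a miRNA raised in many inflamed tissues, at 29690 ± 1883 CPM in normal ulcer and 28470 ± 1520 CPM in diabetic ulcer (SD, n = 2). Of the 21 lists fixed in advance, 19 had at least 3 tested members. Camera called 1 over 6 columns and 2 over the 4 libraries, and no list passed with an estimated correlation, in these fits or in any alternative run, or with fry in either fit. For camera with an estimated correlation, failure was nearly fixed in advance by the few degrees of freedom and decides nothing about a call. Of 165 tested miRNAs on any list, 0 passed edgeR's test over all tested miRNAs and 0 passed adjusted over the list alone, where the smallest adjusted p was 0.188.

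Epithelial miRNAs did not pass. All 8 of the keratinocyte and epithelial list were lower over 6 columns (median log2 -0.34, camera's adjusted p = 0.288), and 7 of 8 over the 4 libraries (median -0.28, adjusted p = 0.397). These counts moved when single columns were left out: 4 of 8 were lower without normal ulcer 1 (median -0.05, adjusted p = 0.574) and 4 of 8 without diabetic ulcer 2 (median -0.15, adjusted p = 0.479). All 8 were lower without normal ulcer 2 (median -0.63) and without diabetic ulcer 1 (median -0.66). The column numbered 3, which is computed from the library left out and its partner, stayed in these fits. The list was called without normal ulcer 2 (adjusted p = 0.0209; there adjusted p = 0.716 with an estimated correlation), at the threshold with library totals (adjusted p = 0.866 with an estimated correlation) and on deposited TPM with a pseudocount of 1 (adjusted p = 0.0387; there adjusted p = 0.716 with an estimated correlation). miR-203-3p, which promotes keratinocyte differentiation, had 37430 and 18410 CPM in normal ulcer 1 and 2 and 32890 and 15020 CPM in diabetic ulcer 1 and 2. miR-205-5p had 3069, 1287, 2756 and 1067 CPM in these libraries in that order, and for both miRNAs library 1 lay above library 2 in each group. All 3 miRNAs of the miR-183 cluster, which is expressed in hair follicles and sensory organs, were lower (median -0.67 over 6 columns and -0.20 over the 4 libraries, adjusted p = 0.361 and 0.811). The median was -1.45 without diabetic ulcer 1 and -0.34 without normal ulcer 1, and 2 of 3 were lower without normal ulcer 1 or without diabetic ulcer 2. The cluster was called on deposited TPM with pseudocounts of 1 and 0.1 (adjusted p = 0.0387 and 0.0455; there adjusted p = 0.716 and adjusted p = 0.746 with an estimated correlation). In that cluster miR-183-5p had 1544 and 737 CPM in normal ulcer 1 and 2, 1340 and 730 CPM in diabetic ulcer 1 and 2, and 58.4 CPM in the column of diabetic ulcer 3.

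Leukocyte miRNAs had 5 of 7 members higher in diabetic ulcer over 6 columns and 6 over the 4 libraries (median log2 0.61 and 0.09, adjusted p = 0.359 and 0.542), and the median was 0.12 without diabetic ulcer 3 and 0.96 without diabetic ulcer 1. miR-142a-3p, which is restricted to blood cells, had 93.7 and 120 CPM in normal ulcer 1 and 2, and 87.0 and 342 CPM in diabetic ulcer 1 and 2. miR-223-3p, a miRNA of neutrophils and other myeloid cells, had 467 ± 94.0 CPM in normal ulcer and 509 ± 283 CPM in diabetic ulcer, and the lymphocyte miRNA miR-150-5p had 113 ± 54.8 and 172 ± 42.7 CPM (SD, n = 2). Inflammation-induced miRNAs went both ways, with 4 of 9 higher over 6 columns and 3 over the 4 libraries (median -0.03 and -0.10, adjusted p = 0.359 and 0.23). The median was 0.07 on deposited TPM and ran from -0.09 to 0.05 when single samples were left out, and the mean over 6 columns was 0.12. In this list miR-146a-5p, a feedback regulator of innate immune signalling, had 1964 ± 192 CPM in normal ulcer and 1563 ± 35.6 CPM in diabetic ulcer, while miR-146b-5p had 462 ± 34.3 and 458 ± 19.8 CPM (SD, n = 2). Of 4 erythroid entries 3 were higher over 6 columns and 1 over the 4 libraries (median 0.13 and -0.17, adjusted p = 0.543 and 0.983), with miR-451a at 248 ± 102 and 219 ± 52.9 CPM (SD, n = 2). The erythroid median was 0.47 without normal ulcer 2 (4 of 4 higher), 0.37 without diabetic ulcer 1, -0.04 without normal ulcer 1 and -0.11 without diabetic ulcer 3 (1 of 4 higher without either of these).

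Skeletal muscle miRNAs varied most between the libraries. Of 7 tested members 5 were lower in diabetic ulcer over 6 columns and 7 over the 4 libraries (median log2 -0.43 and -0.68, adjusted p = 0.543 and 0.492), while the median was 0.01 with limma-voom, 0.02 with library totals, 0.07 on deposited TPM and 0.45 without normal ulcer 2. Without normal ulcer 1 camera called the list lower in diabetic ulcer (median -0.87, adjusted p = 0.000123), and there adjusted p = 0.819 with an estimated correlation. miR-133a-3p had 389 and 3677 CPM in normal ulcer 1 and 2, and 1923 and 1449 CPM in diabetic ulcer 1 and 2. miR-206-3p, a miRNA of regenerating skeletal muscle, had 4222, 13160, 7797 and 2807 CPM in the same order. The adipocyte list had 4 of 7 members higher over 6 columns and over the 4 libraries (median 0.20 and 0.14, adjusted p = 0.361 and 0.75; median -0.05 without diabetic ulcer 2 and 0.37 without normal ulcer 2), with miR-378a-3p at 16660 ± 15470 CPM in normal ulcer and 12680 ± 3953 CPM in diabetic ulcer (SD, n = 2).

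Vascular and stromal lists did not pass. All 5 endothelial miRNAs were higher over 6 columns and 3 over the 4 libraries (median log2 0.09 and 0.03, adjusted p = 0.389 and 0.983; median 0.24 without normal ulcer 1, 0.16 without diabetic ulcer 1 and 0.05 without normal ulcer 2), with miR-126a-3p, the main endothelial miRNA, at 12940 ± 3603 and 13530 ± 5876 CPM (SD, n = 2). Smooth muscle and pericyte miRNAs had 3 of 4 members higher over 6 columns and 2 over the 4 libraries (median 0.11 and -0.01, adjusted p = 0.698 and 0.983; median 0.01 to 0.19 when single samples were left out), with miR-143-3p at 29580 ± 619 CPM in normal ulcer and 32100 ± 8710 CPM in diabetic ulcer (SD, n = 2). In the fibroblast and matrix list of miR-199 and miR-214, 4 of 5 entries were lower over 6 columns and over the 4 libraries (median -0.31 and -0.07, adjusted p = 0.359 and 0.983). The median of that list was -0.07 without diabetic ulcer 3, -0.06 without normal ulcer 1 and -0.62 without diabetic ulcer 1, and miR-214-3p had 198 ± 10.03 and 193 ± 47.5 CPM (SD, n = 2). The collagen-targeting miR-29 list had 3 of 5 members lower over 6 columns and 4 over the 4 libraries (median -0.12 and -0.04, adjusted p = 0.359 and 0.448; median 0.01 on deposited TPM and -0.26 to -0.02 when single samples were left out), and its most abundant member miR-29a-3p had 1681 ± 7.42 and 1492 ± 182 CPM (SD, n = 2). Of the hypoxia list, which was too small for camera, miR-210-3p had 38.3 ± 16.3 and 28.5 ± 2.59 CPM and miR-210-5p had 1.69 ± 0.713 and 2.27 ± 0.756 CPM (SD, n = 2).

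Lists related to growth did not pass. let-7 and miR-98 had 7 of 9 members lower over 6 columns and 8 over the 4 libraries (median log2 -0.13 and -0.10, adjusted p = 0.359 and 0.397; median -0.22 to -0.09 when single samples were left out), where near-identical members may share reads, with let-7f-5p at 27710 ± 394 CPM in normal ulcer and 27090 ± 2434 CPM in diabetic ulcer (SD, n = 2). Of the proliferation list of miR-17-92 and its paralogues 8 of 13 were lower in both fits (median -0.05 and -0.04, adjusted p = 0.359 and 0.448; median 0.02 with library totals or deposited TPM and -0.18 to -0.02 when single samples were left out), with miR-25-3p at 1685 ± 48.2 and 1731 ± 114 CPM (SD, n = 2). The miR-15-16 family had 4 of 7 members lower over 6 columns and 6 over the 4 libraries (median -0.44 and -0.22, adjusted p = 0.359 and 0.23; median -0.19 without diabetic ulcer 3), and miR-195a-5p had 235 ± 28.9 and 188 ± 16.9 CPM (SD, n = 2). The miR-34 list, which is linked to p53 and senescence, had 3 of 5 members higher in both fits (median 0.21 and 0.10, adjusted p = 0.693 and 0.874; median 0.10 to 0.27 when single samples were left out), with miR-34c-5p at 358 ± 45.8 and 397 ± 37.3 CPM (SD, n = 2); its mean log2 difference over 6 columns was -0.08, of the opposite sign to its median.

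miRNAs of other tissues were also measured. The neural and Schwann list had 3 of 5 members lower in both fits (median log2 -0.10 over 6 columns and -0.37 over the 4 libraries, adjusted p = 0.359 and 0.203; median -0.34 without diabetic ulcer 3 and 0.00 without normal ulcer 2), with miR-338-3p at 19.8 ± 8.23 CPM in normal ulcer and 12.2 ± 1.33 CPM in diabetic ulcer (SD, n = 2). The liver and gut list had 3 of 5 lower over 6 columns and 4 over the 4 libraries (median -0.17 and -0.26 in these fits, 0.07 without diabetic ulcer 1, 0.03 without diabetic ulcer 2 and 0.51 on deposited TPM; mean 0.20 over 6 columns; adjusted p = 0.693 and 0.192), with the liver miRNA miR-122-5p at 4.76 ± 1.16 and 2.62 ± 0.265 CPM (SD, n = 2). miR-122-5p had 7.47 CPM in the column of diabetic ulcer 3, and it was called in the opposite direction on deposited TPM with a pseudocount of 10 (log2 0.61). Of the pigment cell list, which was too small for camera, miR-204-5p had 21.3 ± 0.401 and 17.5 ± 2.74 CPM and miR-211-5p had 8.91 ± 7.73 and 12.4 ± 9.84 CPM (SD, n = 2).

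**Figure D3:**
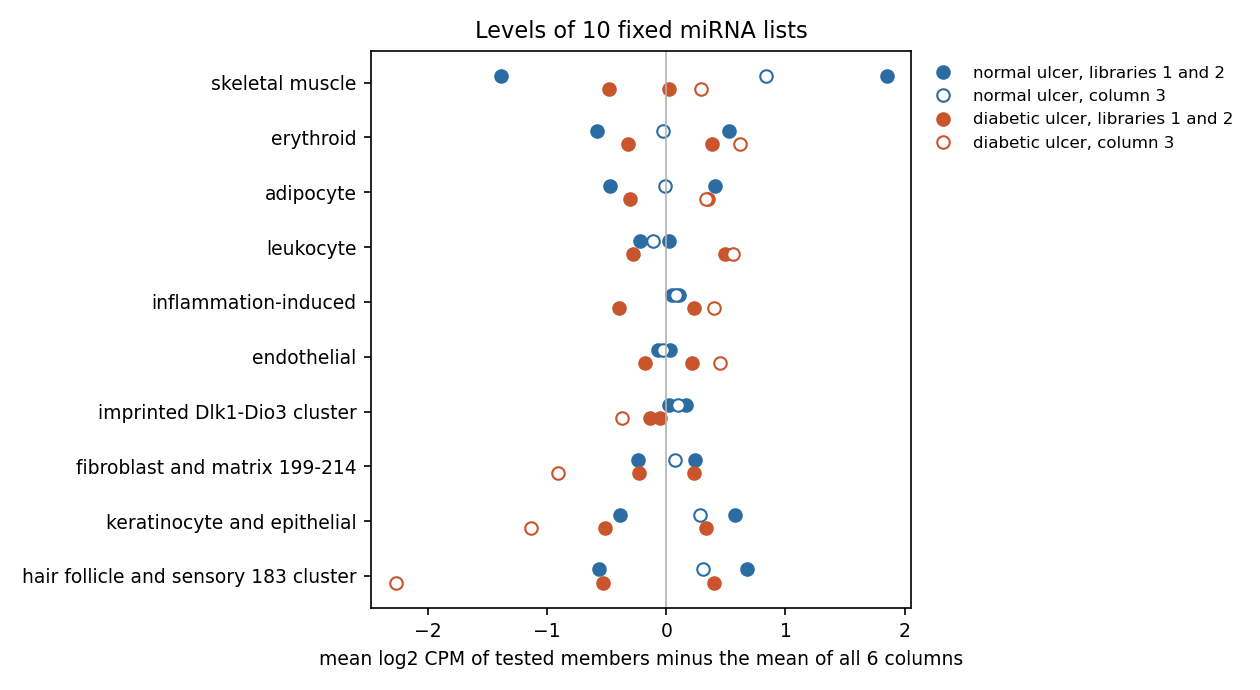
Mean log2 CPM of the tested members of 10 fixed lists, minus the mean of libraries 1 and 2 of both groups. The axis label names all 6 columns, but the mean subtracted is that of these 4 libraries. Normal ulcer is in blue and diabetic ulcer in orange. Filled points are libraries 1 and 2 and open points the columns numbered 3; skeletal muscle spans -1.39 to 1.85 within normal ulcer, and for the keratinocyte list library 1 lies above library 2 in both groups (0.58 and -0.39 in normal ulcer, 0.33 and -0.51 in diabetic ulcer).

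The authors' deposited table of DESeq2 results does not follow the sample labels. Its header calls the code of the normal ulcer samples case and that of the diabetic ulcer samples control. In the authors' deposited table the case mean equalled 0.283 times normal ulcer 1 plus 0.412 times normal ulcer 2 plus 0.329 times diabetic ulcer 1, within 0.1% for 647 of the 647 miRNAs shared with the count table. The control mean of the authors' deposited table equalled 0.931 times diabetic ulcer 2 alone for 646 of them. It therefore set 3 libraries against 1, and neither column numbered 3 entered these means. Whether the labels or the table's header name the groups rightly is open, and so is the group of the library labelled diabetic ulcer 1. Every direction above follows the labels, and an exchange of the group names would turn each of them.

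The authors' deposited table listed 23 of 649 miRNAs with p under 0.05, of which 9 were higher and 14 lower in case. The authors' deposited table gave 1 miRNA with q under 0.05, miR-142a-3p, with a log2 fold change of -1.68 for case over control (q = 0.00329), that is, higher in the control mean. Next in the authors' deposited table were miR-129-5p with a log2 fold change of -2.60 (q = 0.0683) and miR-31-5p, a keratinocyte miRNA of wounds, with 1.86 (q = 0.132). Of the 23, 22 were tested here, all 22 had the direction of the authors' deposited table once its sign was turned to diabetic over normal, and 1 had an unadjusted p under 0.05 in edgeR. Across 438 miRNAs, which are not independent replicates, the log2 differences over 6 columns correlated with those of the authors' deposited table with Spearman's rho 0.759 and Pearson's r 0.719. Over the 4 libraries (443 miRNAs) the values were 0.603 and 0.621. Both sides rest on the same libraries, so a positive correlation arises without any group effect. In the TPM column of diabetic ulcer 3, 21 miRNAs equalled the mean of diabetic ulcer 1 and 2 (within 1e-06 TPM plus a fraction of 1e-06 of the mean), and 20 of these were among the 23 with p under 0.05 in the authors' deposited table.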

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

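The settings on the 4 independent libraries, camera on deposited TPM and the estimated correlation in alternative settings were chosen only after the result was seen; all others were fixed before the data were examined. edgeR called 0 miRNAs under each alternative of scaling, filter, removed miRNAs, block and 2-fold threshold, and limma-voom called 0. DESeq2 on 6 columns called 6 miRNAs, and 2 adjusted over the list alone, against 0 and 0 on the 4 libraries. Leaving out each sample gave 0 to 5 calls, 0 to 1 adjusted over the list alone and 1 to 3 lists; the 5 calls came without diabetic ulcer 1, and the 2 and 3 lists without normal ulcer 1 and normal ulcer 2. On deposited TPM the calls were 0, 0 and 1 (miR-122-5p, at 0.61 against -0.21) with pseudocounts 1, 0.1 and 10, and 1 adjusted over the list alone with each; pseudocounts 1 and 0.1 put the median of all miRNAs at 0.14 and 0.17, against 0.04. The cause was not tested. Camera called 2 lists with library totals, 4, 3 and 1 on deposited TPM with pseudocounts 1, 0.1 and 10, and 2 on the 4 libraries, and the cause was not tested. With an estimated correlation camera called 0 lists in every setting run with one, where its few degrees of freedom leave little room for a call. The imprinted cluster was called in every setting run with the preset correlation.

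miR-1a-3p, at -0.34 in the reported fit, took the opposite sign under limma-voom (0.11), library totals (0.02), the replicate block (0.12) and TPM with each pseudocount (0.16), and ranged from -0.77 to 0.53 when each sample was left out; the cause was not tested. The 10 miRNAs with the smallest p kept their sign under every alternative that tested them, and 7 of those values passed. These miRNAs were chosen by their p in the same samples that each alternative reuses in full or in part. A kept sign is therefore likely and is no further support. The passing values came from DESeq2 over all columns and from edgeR without diabetic ulcer 1, where columns that follow from others stayed in. None came from the 4 independent libraries. The correlation with the authors' values kept its sign throughout, from 0.528 to 0.848.

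The labels do not say whether the sample numbers pair the samples, and 2 pairs of independent libraries are too few to take them as pairs. Deviations of same-numbered samples correlated at 0.398 and 0.331 for numbers 1 and 2, whose libraries were also the closest (0.49 and 0.636), and the split of the 4 libraries by number called 11 miRNAs and 5 lists, against 0 and 2 for the real split. These values describe 1 feature of the 4 libraries, which with 2 libraries per group can match the numbers by chance and does not show that they pair. The value for number 3, 0.031, comes from columns that follow from others and decides nothing. With the replicate block edgeR called 0 of 438 (51 at an unadjusted p under 0.05, against 48) and, on the 4 libraries, 0 of 443 (20, against 4). Camera with the replicate block called 3 lists, among them the imprinted cluster. The others were the epithelial list (adjusted p = 0.0274, and 0.105 with a block on the 4 libraries) and the wound list (0.0315 and 0.0195). On the 4 libraries camera called 2 lists with a block and 2 without. With an estimated correlation, camera with the block gave these 3 lists adjusted p = 0.771, and 0.952 on the 4 libraries. Depth limits the rare miRNAs, several of which rest on under 60 counts per library.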

Other observations

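All tests in this part were chosen only after the result was seen.

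Muscle and epithelial miRNAs differed between the libraries of a group. From normal ulcer 1 to normal ulcer 2, all 7 tested muscle miRNAs were higher (median log2 difference 2.23), while 7 of 8 epithelial miRNAs were lower (median -1.02). From diabetic ulcer 1 to diabetic ulcer 2 the medians were 0.64 for muscle and -0.97 for epithelium, but 3 of the 7 muscle miRNAs were lower, miR-206-3p (-1.47), miR-133a-3p (-0.41) and miR-133a-5p (-0.15). miR-499-5p, encoded in a slow-muscle myosin gene and chosen here after its values were seen, had 0 counts in normal ulcer 1, which allows up to 0.335 CPM without TMM scaling. It had 505 counts in normal ulcer 2, 1 in diabetic ulcer 1 and 19 in diabetic ulcer 2.

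For the normal ulcer libraries, an effect of scaling is argued against by the difference of 3.25 (log2) between the muscle and epithelial medians, since a scaling factor moves both lists alike. A candidate explanation is more skeletal muscle in the tissue of normal ulcer 2, which may account for the direction of 7 of 7 muscle miRNAs. Among members with at least 1000 counts in both normal libraries, the differences ran from 1.64 (miR-206-3p) to 3.24 (miR-133a-3p). A single difference in the amount of muscle is therefore not shown to account for their sizes. For the diabetic ulcer libraries, a single difference in the amount of muscle is argued against. The 5 muscle miRNAs with at least 1000 counts in both span 2.76 log2 units, from miR-206-3p at -1.47 to miR-133b-3p at 1.29. Differences in muscle state or in the site sampled stay open and untested.

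The sample numbered 3 of each group follows the other samples of its group. For normal ulcer 3, both an independent library and pooled RNA of samples 1 and 2 sequenced again are argued against by a variance of 0.0008 of the Poisson variance, against at least 0.757 in simulated libraries. Values computed from the other columns remain, and 98.6% of its counts lie within 1 read of a weighted sum. For diabetic ulcer 3, an independent library is argued against, since 84.3% of miRNAs lie within 1% of a linear formula against at most 10.7% in the 54 mixed choices of columns; computed values remain a candidate explanation, with 85.1% of TPM values within 0.1% of the formula. No biological explanation was tested, and the tables do not say how or why the columns were made.

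The lower values of the imprinted cluster in diabetic ulcer do not rest on the columns numbered 3, since camera's adjusted p over the 4 libraries was 0.000437. Whether the difference follows the group is open. Of the 2 other splits of the 4 libraries, that of normal ulcer 1 with diabetic ulcer 2 gave a camera p of 0.0122 for the cluster, and that of normal ulcer 1 with diabetic ulcer 1 gave 0.547. The real split gave 2.3e-05, or p = 0.0665 with an estimated correlation. With an estimated correlation the 2 other splits gave camera p of 0.4 and 0.843, in the same order. Members of 1 locus may vary together between libraries for reasons other than diabetes, and the 4 libraries are too few to tell.

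The 6 columns have 10 splits, too few for a share under 0.05, and 2 of the columns follow from others. The real split called 0 miRNAs with edgeR and the highest other called 0; since any count reaches 0, all 10 splits count and the test decides nothing. The real split called 1 list and the highest other called 6, with at least as many as the real one in 8 of 10. Among the 3 splits of the 4 independent libraries, the pair of libraries numbered 1 against the pair numbered 2 gave 11 called miRNAs and 5 called lists, against 0 and 2 for the real split. What sets these libraries apart is not in the labels.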
